A study of Mus musculus with 6 samples.

How the data were processed

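Messenger RNA was sequenced from the livers of 6 mice of the C57BL/6 strain, aged 6 weeks, in 3 groups of 2. Control wild-type mice (replicates 3 and 6) received 200 µL of phosphate-buffered saline into the abdominal cavity. Wild-type mice (replicates 1 and 4) and mice lacking Optn (replicates 4 and 5) received acetaminophen at 500 mg per kg, and all livers were taken after 6 h, per the labels. Per the labels' protocols, poly(A) RNA was selected and sequenced as paired ends. The same protocols speak of RNA from an adipose type, although the tissue label of each sample is liver, and this was not resolved. The labels number the replicates but do not say whether a number stands for a cage, day or batch.

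The deposited table lists a whole-number count per gene and library, with no normalization, per the file headers and the values. The counter, its use of strand, and whether counts are tallied reads or rounded estimates are not given in the sources used here. The same table holds a deposited FPKM value (fragments per kilobase of gene model and per 1e6 counted fragments) for each gene and library. A gene's length implied by count, total and FPKM differed between libraries by a median of 0.96%. All 207863 values with a count of 0 are listed at an FPKM of 0.0001. Per the submitters' processing notes, Bowtie 0.12.2 was used and mm8 was the genome build. The coordinates in the table equal those of the GRCm38 annotation GENCODE M21 for 51991 of its 55144 genes (94.3%), so coordinates are given as GRCm38. Of the 55385 genes in the table, 28158 have a count of 0 in all libraries. Every entry names a gene, and every column of values was matched to a sample by its title.

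Total counts were 59.1 and 75.9 M (1e6 counts) in control replicates 3 and 6, 66.0 and 71.1 M in wild-type acetaminophen replicates 1 and 4, and 77.3 and 62.5 M in knockout acetaminophen replicates 4 and 5. A count of 0 allows up to 3 counts, or 0.0507 CPM in the smallest library, and such floors cover counting error only. As a check for a library deposited under more than 1 name, replicate pairs were compared with sampling noise, and none lay within it (mean chi-square per gene 106.1, 133.5 and 259.2 in the control, wild-type acetaminophen and knockout groups). This does not show that the replicates are independent. Nothing in the labels says more about how the mice were raised or grouped, and p-values measure the spread between these samples.

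The tests had been designed for FPKM values, before the data were examined, as limma with a mean-variance trend on log2(FPKM + 0.5). Because the table also holds counts, the main test became edgeR's quasi-likelihood test on the counts as deposited, and the limma fit as designed became an alternative. The rest of the design was kept: all 6 libraries in one model of 3 group means, with no covariates. Genes with a mean FPKM of at least 0.5 (11677 genes) were tested at a Benjamini-Hochberg adjusted p under 0.05. Trimmed-mean (TMM) scaling was not part of the design and came with the change to counts. The common biological coefficient of variation was 0.277, with 3 residual degrees of freedom and 2.93 prior degrees of freedom. An exact permutation test of 2 mice against 2 cannot give a two-sided p below 0.333, so no such test was used. Comparisons were acetaminophen against saline in wild type, knockout against wild type after acetaminophen, and treated knockout against wild-type control. No knockout mice without acetaminophen were analysed here.

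A set of 31 gene lists and 13 lists of cell type markers had been fixed beforehand from general knowledge of liver biology. By symbol, 766 members matched entries, 1 matched through a synonym and 3 did not match. Lists were tested against all other genes with limma's camera on log2 CPM, with a preset inter-gene correlation of 0.01 and adjustment over the 43 lists with at least 2 measured members, and again with an estimated correlation. Members past the gene test were counted with p adjusted over all genes and with p adjusted over the list alone. Genes named in the text were Optn, a set of anchor genes, up to 4 members with the smallest p per list, and, for the first 2 comparisons, the 8 largest rises and 8 largest falls among genes past the threshold with groups that do not overlap and a mean FPKM of at least 1. Predicted genes, pseudogenes and genes with only an identifier were left out of these 8. Where fewer than 8 passed, genes with the smallest p filled the list and are given as not past the threshold.

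Transcripts of other tissues were summed over lists of markers written after the libraries had been compared. They divide the libraries into 2 sets of 3, described in the report, and a model with this set as a term, which has 2 residual degrees of freedom, was added after seeing the data. Only the controls were divided between the sets, so the set effect in this model rests on control replicate 6 against control replicate 3. With the term, treated wild type is in effect compared with control replicate 3 alone, and treated knockout with control replicate 6 alone. The term is therefore no independent check and may carry any difference between these control mice. Errors are SD over the 2 mice of a group or an approximate SE of a log2 fold change. This SE is the size of the log2 fold change over the square root of edgeR's quasi-likelihood F. A fold against a group with a count of 0 in both libraries is a lower bound against 3 counts over the group, and a ratio to 1 to 3 counts has an exact 95% counting interval.

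The test was tried on simulated data for the 11677 genes, with known genes changed in 1 group. For acetaminophen in wild type it recovered 14.9% of genes changed 2-fold, 88.1% of those changed 4-fold and 83.3% of those changed 8-fold. Of the 131 genes called in that simulation, 7 were false calls. For the knockout comparison the shares were 19.4%, 74.6% and 92.4%, with 13 false calls among 137 simulated calls. For treated knockout against control they were 14.9%, 77.6% and 90.9%, with 9 false calls among 132 simulated calls. Alternatives were other filters, scalings, pseudocounts, priors, library weights, a fold minimum, the 4 libraries of a comparison alone, DESeq2, and leaving out each library. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.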

Results

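Liver transcripts were counted in 6 mice, 2 per group: wild-type controls given saline, wild-type mice given acetaminophen and Optn knockout mice given acetaminophen. Acetaminophen (paracetamol) at high dose is bioactivated by cytochrome P450 enzymes in hepatocytes and is a standard model of drug-induced liver injury. Optn encodes optineurin, an autophagy receptor that takes part in the removal of damaged mitochondria (mitophagy). Total counts ran from 59.1 M in control replicate 3 to 77.3 M in knockout replicate 4. Albumin alone took between 6.69% of counts, in knockout replicate 4, and 9.94%, in wild-type acetaminophen replicate 1.

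Optn itself (ENSMUSG00000026672, chromosome 2, 5020642 to 5064045, minus strand, GRCm38) was measured first, since it checks the genotype labels. Its FPKM was 20.95 and 18.73 in control replicates 3 and 6, 9.17 and 9.19 in wild-type acetaminophen replicates 1 and 4, and 0.32 and 0.46 in knockout replicates 4 and 5. It was lower in treated knockout than in treated wild type by a log2 fold change of -4.59 ± 0.21 (SE, edgeR adjusted p = 0.00423, and 0.0573 with the library set as a term, described below). Optn also fell with acetaminophen in wild type (log2 fold change -0.90 ± 0.18, edgeR adjusted p = 0.027, and 0.0679 with the library set as a term). Counts of 101 and 118 remained on the gene in the 2 knockout livers. No library went against its genotype label.

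**Figure D1:**
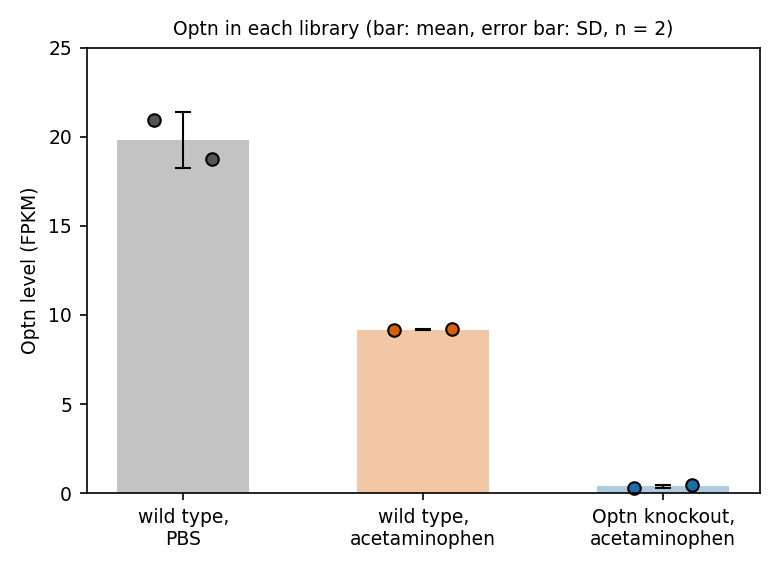
Optn FPKM (vertical axis) in each of the 6 livers by group, with a point per mouse and the mean ± SD (n = 2) of the group. Controls lie at 20.95 and 18.73, treated wild type at 9.17 and 9.19, and treated knockout at 0.32 and 0.46.

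Traces of transcripts from other tissues separated the libraries in a way the groups do not explain. Skeletal muscle genes (12 markers, among them Ckm, Acta1 and Myh4) gave 106, 67.45 and 80.24 CPM (counts per 1e6 counts of the library) in control replicate 3 and wild-type acetaminophen replicates 1 and 4, and at most 1.01 in the other libraries. Intestinal genes (12 markers, among them Muc2, Clca1 and Zg16) gave 40.35, 42.82 and 68.19 CPM in control replicate 6 and knockout replicates 4 and 5, and at most 0.30 elsewhere. Both treated groups therefore lay wholly within 1 set each, and only the controls were divided. Of the 10 ways to split 6 libraries into 3 and 3, this one had 116 genes at least 3 times apart between sides, and the other splits had at most 56. Wild-type acetaminophen replicate 4 also held neural transcripts, with 274.7 CPM of neuron markers such as Snap25, Syp and Stmn2 against 2.22 to 12.63 elsewhere. It held 80.33 CPM of glial markers against at most 5.40, and 37.78 of hypothalamic and pituitary markers such as Oxt, Avp and Gh against at most 0.66. In that library 332 genes were over 10 times above every other library. Heart markers gave at most 0.82 CPM, kidney markers at most 0.0563 and lung markers 0.70 to 6.52, most of it from Sftpa1. A first principal component with 52.4% of the variance separated controls from treated livers, and a second with 21.8% placed the 3 libraries with intestinal traces at -28.7 to -32.3 and the others at 9.80 to 58.9.

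**Figure D2:**
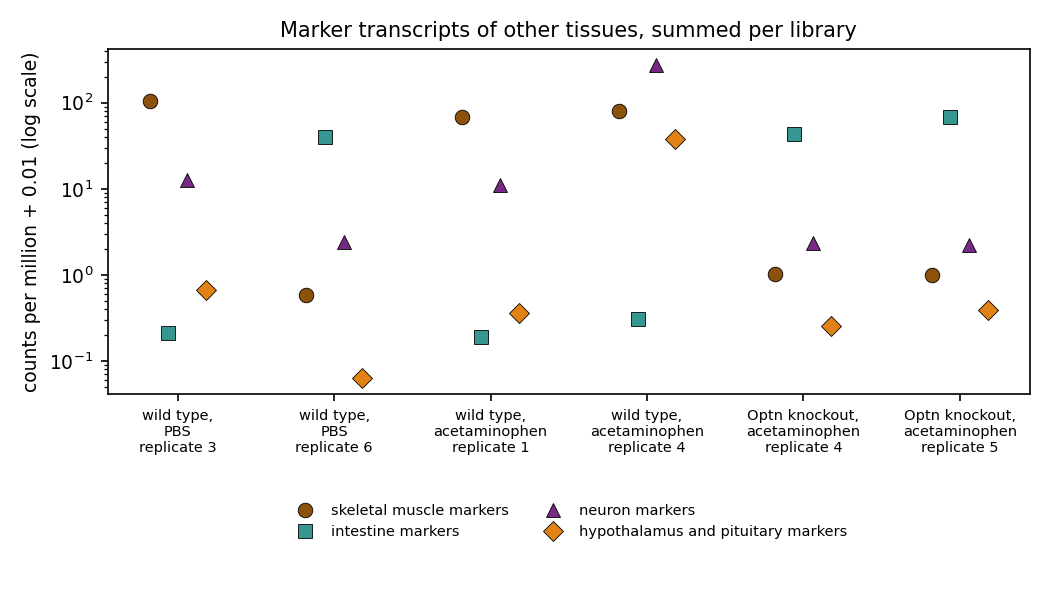
Summed CPM (logarithmic axis) of marker genes of other tissues in each library. Skeletal muscle markers reach 67.45 to 106 in 3 libraries and intestinal markers 40.35 to 68.19 in the other 3, and neuron markers reach 274.7 in wild-type acetaminophen replicate 4.

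The first comparison asks what acetaminophen does to the liver transcriptome of wild-type mice within 6 h. Immediate early transcription factors, markers of neutrophils and stress genes rose, and the fatty acid ω-hydroxylases Cyp4a10 and Cyp4a14 fell. Atf3, a stress-induced transcription factor, rose from an FPKM of 0.86 ± 0.09 (SD, n = 2) to 165.9 ± 7.72 (n = 2). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 26.5 ± 4.48 to 3.03 ± 0.45. Of 11677 genes tested, 976 rose and 691 fell (edgeR adjusted p under 0.05), and 3767 had an unadjusted p under 0.05.

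The largest rises among named genes included 4 transcription factors and markers of infiltrating cells. Fos (chromosome 12, 85473890 to 85477273) rose by 9.46 ± 0.62 on the log2 scale, Fosb by 8.50 ± 1.45, Atf3 (chromosome 1, 191170296 to 191218039) by 7.80 ± 0.19 and Egr1 (chromosome 18, 34859823 to 34864984) by 7.80 ± 0.21, with edgeR adjusted p of 0.00179, 0.0182, 0.000192 and 0.000192. Il1r2, a decoy receptor for interleukin 1, had a count of 0 in both controls and was at least 296-fold higher after acetaminophen (edgeR adjusted p = 0.00502). Stfa2l1, a stefin A family gene of neutrophils, was also at 0 in both controls and was at least 26.8-fold higher (edgeR adjusted p = 0.00883). Retnlg, another neutrophil gene, rose by 7.00 ± 1.09 and Sprr1a, a cornified envelope protein, by 8.14 ± 1.23 (edgeR adjusted p = 0.0144 and 0.0138). The controls had 0 and 6 counts of Fosb and 0 and 4 of Sprr1a, and Fosb had 195 and 1820 in the treated mice. The fitted log2 fold change of Sprr1a became 12.11 with the library set as a term, and that of Fosb became larger still, so the sizes of these rises are uncertain. The largest falls were those of Tmem170b, a transmembrane protein gene (log2 fold change -4.80 ± 0.25), Mup8, a major urinary protein (-4.39 ± 0.55), Cyp4a14 (-3.91 ± 0.41), Nrep (-3.80 ± 0.50), the clock gene Per3 (-3.25 ± 0.36), the acyl-CoA thioesterase Acot3 (-3.15 ± 0.59), Cyp4a10 (-2.97 ± 0.21) and Cyp7a1 (-2.91 ± 0.19), with edgeR adjusted p between 0.00144 and 0.0228. Mup8 belongs to a family of near-identical copies, so its own count is uncertain.

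**Figure D3:**
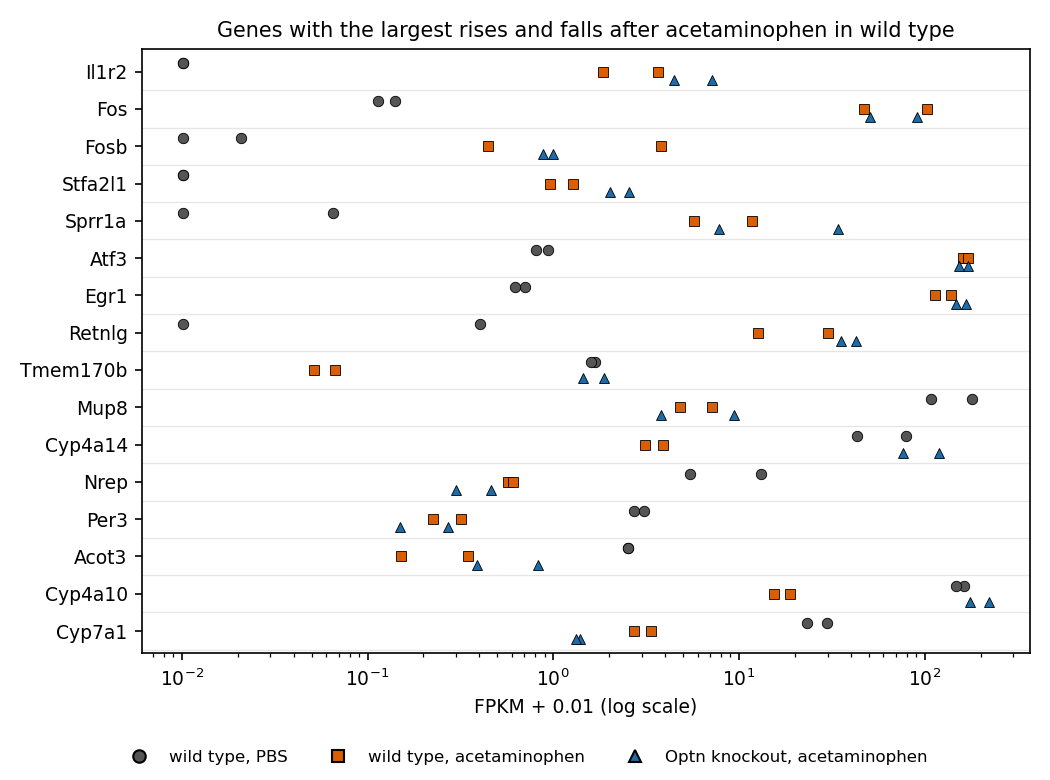
FPKM per mouse (logarithmic axis) of the 16 named genes with the largest rises and falls after acetaminophen in wild type, in all 3 groups. Atf3 goes from a mean of 0.86 in controls to 165.9, and Cyp7a1 from 26.5 to 3.03.

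Stress and signalling lists shifted upward. Of 23 measured immediate early genes, 21 rose, and 21 did so adjusted over the list alone, with a median log2 fold change of 4.65 (camera, limma, adjusted p = 1.46e-19, and adjusted p = 0.0804 with an estimated correlation). Ier2 rose by 3.79 ± 0.16 and Fosl2 by 2.71 ± 0.12. Of 23 endoplasmic reticulum and integrated stress response genes, 13 rose and 2 fell, or 16 and 3 adjusted over the list alone (camera adjusted p = 6.00e-06, and adjusted p = 0.457 with an estimated correlation), and 0 fell in edgeR without wild-type acetaminophen replicate 4 or with the library set as a term. Among them were Psat1 of serine synthesis (4.30 ± 0.20), the transcription factor Ddit3 (CHOP, 4.60 ± 0.27) and Sesn2 (3.30 ± 0.25). The secreted stress hormones of this list also rose, Fgf21 by 4.61 ± 0.61 and Gdf15 by 5.85 ± 0.45 (edgeR adjusted p = 0.00965 and 0.00243). Of 15 p53 targets, 9 rose, or 10 adjusted over the list alone (camera adjusted p = 3.54e-06, and adjusted p = 0.267 with an estimated correlation), including Btg2 (5.72 ± 0.32), Plk3 (3.17 ± 0.19) and Trp53inp1 (3.17 ± 0.20). The cell cycle inhibitor Cdkn1a, in the same list, rose by 6.48 ± 0.63 (edgeR adjusted p = 0.00433). Of 20 antioxidant and glutathione genes controlled by NRF2, 5 rose, or 10 adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.532 with an estimated correlation). Hmox1, haem oxygenase 1, went from an FPKM of 6.64 ± 4.39 to 641.1 ± 42.95 (n = 2 each), Gclc of glutathione synthesis rose by 1.67 ± 0.39 (edgeR adjusted p = 0.0414), and Nqo1 had a log2 fold change of 0.03 ± 0.32 (edgeR adjusted p = 0.967). Without wild-type acetaminophen replicate 4, and likewise with the library set as a term, 2 of these 20 genes passed. The list did not pass camera without wild-type acetaminophen replicate 4 (adjusted p = 0.0992) or control replicate 6 (0.13), or at a mean FPKM of at least 5 (0.0674). Of 16 metallothionein and iron genes, 6 rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00602, and adjusted p = 0.457 with an estimated correlation). The zinc transporters Slc39a14 (1.72 ± 0.20) and Slc30a1 (1.17 ± 0.17) rose, and the iron exporter Slc40a1 fell (-1.26 ± 0.16).

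Genes of inflammation and of blood cells were higher as well. Of 22 acute phase proteins, 10 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 1.04e-06, and adjusted p = 0.532 with an estimated correlation), and 0 fell in edgeR without wild-type acetaminophen replicate 4 or with the library set as a term. Lcn2 rose by 5.32 ± 0.71, Steap4 by 3.49 ± 0.17 and the fibrinogen chain Fgg by 1.61 ± 0.15, whereas Saa1 had a log2 fold change of 3.02 ± 0.83 (edgeR adjusted p = 0.0642). Of 19 cytokine, chemokine and NF-kB target genes, 7 rose, or 15 adjusted over the list alone (camera adjusted p = 2.12e-06, and adjusted p = 0.532 with an estimated correlation). Cxcl10 rose by 3.20 ± 0.31 and Cxcl1 by 3.43 ± 0.61, Ccl2 had a log2 fold change of 4.62 ± 1.20 (edgeR adjusted p = 0.0555, and 0.0347 with the library set as a term), and Il6 was below the filter with at most 31 counts in a library. Without wild-type acetaminophen replicate 4, 12 of these 19 genes passed, and 4 did with the library set as a term. Of 11 neutrophil markers, 8 rose, or 10 adjusted over the list alone, with a median log2 fold change of 5.02, or 4.84 with genes at 0 in controls put at their bound (camera adjusted p = 2.45e-07, and adjusted p = 0.457 with an estimated correlation). S100a8 and S100a9 rose by 4.84 ± 0.53 and 5.53 ± 0.58. Of 8 markers of infiltrating monocytes, 5 rose, or 7 adjusted over the list alone, among them Chil3 (4.23 ± 0.32) and Cd14 (5.42 ± 0.51; camera adjusted p = 1.19e-05, and adjusted p = 0.457 with an estimated correlation). Of 6 red blood cell genes, 5 rose, or 6 adjusted over the list alone, with Hbb-bs up by 3.22 ± 0.44 (camera adjusted p = 0.000731, and adjusted p = 0.532 with an estimated correlation). The near-identical globin copies make each single globin count uncertain. Of 5 platelet markers, 4 rose under either adjustment, including adjusted over the list alone, with Pf4 up by 3.73 ± 0.39 (camera adjusted p = 0.000731, and adjusted p = 0.532 with an estimated correlation). With the library set as a term, 2 of the 5 passed. Of 4 T and NK cell genes, 3 rose, also adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.532 with an estimated correlation), 2 without wild-type acetaminophen replicate 4 and 0 in edgeR with the library set as a term. Camera did not pass T and NK cell genes without control replicate 6 (adjusted p = 0.119) or knockout replicate 4 (0.0507).

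Of the metabolic lists, 4 shifted downward by camera. Of 24 fatty acid oxidation and PPAR-alpha target genes, 3 rose and 8 fell, or 3 and 14 adjusted over the list alone (camera adjusted p = 0.000674, and adjusted p = 0.61 with an estimated correlation). The microsomal ω-hydroxylases Cyp4a10 and Cyp4a14 and the pantetheinase Vnn1 (-2.19 ± 0.24) fell, and the lipid droplet protein Plin2 rose (1.13 ± 0.15). Without wild-type acetaminophen replicate 4, 1 rose and 3 fell, and with the library set as a term 1 rose and 6 fell. Of 19 genes of pericentral hepatocytes, the zone around the central vein, 6 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00019, and adjusted p = 0.532 with an estimated correlation). Among those that fell were Cyp2a5 (-1.96 ± 0.29), glutamine synthetase Glul (-1.38 ± 0.25) and Oat (-1.28 ± 0.24), and the amino acid transporter Slc1a4 rose (1.64 ± 0.23). Of 15 lipogenesis genes, 4 fell and 1 rose, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0357, and adjusted p = 0.532 with an estimated correlation). Elovl6 (-1.54 ± 0.20), Srebf1 (-0.92 ± 0.14) and Fads2 (-1.14 ± 0.20) fell while Thrsp rose (1.39 ± 0.13). Without wild-type acetaminophen replicate 4, 2 lipogenesis genes fell, and with the library set as a term 1 did. Of 22 cholesterol synthesis genes, 0 passed in edgeR, over all genes or adjusted over the list alone, although the list was lower by camera (adjusted p = 0.031, and adjusted p = 0.766 with an estimated correlation). In that list 7 of the 22 genes had an unadjusted p under 0.05, all lower. This is close to the share over all tested genes in either direction, 3767 of 11677. Limma and DESeq2 called 2 and 5 genes of the list. The hepatocyte list, by contrast, passed upward, with 1 riser of 12 genes, Fgb (1.42 ± 0.20), also adjusted over the list alone (camera adjusted p = 0.0422, and adjusted p = 0.532 with an estimated correlation). Scaling by total count alone ended the camera calls of lipogenesis (adjusted p = 0.0902), cholesterol synthesis (0.0701) and hepatocyte genes (0.119), and under it nuclear-encoded respiratory chain genes passed downward (0.0243) and Kupffer cell genes upward (0.017). Without control replicate 3 these 3 calls also ended (camera adjusted p = 0.118, 0.619 and 0.0826), as they did without wild-type acetaminophen replicate 1 (0.104, 0.104 and 0.223), and the hepatocyte call ended without control replicate 6 (0.0984). At a mean FPKM of at least 5, lipogenesis (camera adjusted p = 0.0649) and cholesterol synthesis (0.0502) did not pass, whereas bile acid genes passed downward (0.0462) and apoptosis genes upward (0.0246).

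Several lists did not pass camera after acetaminophen, with adjusted p between 0.065 and 0.937. Of 19 genes of acetaminophen bioactivation and conjugation, 2 fell, Cyp2a5 and Cyp2e1 (-0.81 ± 0.19, edgeR adjusted p = 0.0441), and 1 did adjusted over the list alone. Cyp2e1 is the main P450 that bioactivates acetaminophen. Among 17 heat shock proteins, 4 rose and 2 fell under either adjustment, including adjusted over the list alone, with Hspb8 up by 1.97 ± 0.13, and Hspa1b had an FPKM of 2.40 and 24.15 in the 2 treated wild-type mice. The mitophagy list had 1 riser of 23 (also adjusted over the list alone), the autophagy receptor Sqstm1 (1.82 ± 0.16), while Pink1 had a log2 fold change of 0.14 ± 0.15 (edgeR adjusted p = 0.574). The core autophagy list had 2 risers of 28, Ulk1 (1.30 ± 0.15) and Atg12 (0.63 ± 0.12), and 3 risers and 2 fallers adjusted over the list alone. Of 25 lysosomal genes 1 rose, Ctsl (1.90 ± 0.21), also adjusted over the list alone. None of 47 nuclear-encoded respiratory chain genes passed in edgeR, over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and limma called 5 and DESeq2 3. Of 13 mitochondrially encoded genes 2 rose, mt-Atp6 (2.32 ± 0.22) and mt-Nd6 (0.92 ± 0.19), and of 20 mitochondrial chaperones, proteases and biogenesis factors Clpx rose (1.57 ± 0.12) and Esrra fell (-1.33 ± 0.13), with the same counts adjusted over the list alone. The gluconeogenesis list had 3 risers and 3 fallers of 16 (5 and 4 adjusted over the list alone), with the insulin-like growth factor binding protein Igfbp1 up by 6.27 ± 0.26 and Pck1 at -0.17 ± 0.19 (edgeR adjusted p = 0.595). The circadian clock list had 5 and 5 of 16 (5 and 6 adjusted over the list alone), with Nr1d1 up by 3.22 ± 0.26. Apoptosis and necroptosis genes had 7 risers and 2 fallers of 18 (8 and 4 adjusted over the list alone), with Mcl1 up by 1.49 ± 0.13 and the caspase-8 regulator Cflar down (-2.12 ± 0.27). EdgeR without wild-type acetaminophen replicate 4 passed as risers and fallers 2 and 2 heat shock, 1 and 0 core autophagy, 1 and 0 mitochondrially encoded, 2 and 2 gluconeogenesis, 3 and 5 clock and 0 and 1 bioactivation genes. The counts with the library set as a term were 1 and 0 for heat shock, core autophagy and mitochondrially encoded genes, 3 and 5 for the clock and 3 and 2 for apoptosis. Heat shock genes passed camera upward without wild-type acetaminophen replicate 1 (adjusted p = 0.0106).

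Counts for the remaining lists are given as risers and fallers, with those adjusted over the list alone after them. Urea cycle and amino acid catabolism had 4 and 1 of 20 (6 and 1), periportal hepatocyte genes 3 and 0 of 18 (3 and 0), bile acid synthesis and transport 0 and 2 of 17 (0 and 4), cell cycle 1 and 2 of 10 (1 and 2), and interferon-stimulated genes 2 and 3 of 26 (3 and 3) in edgeR. Male-biased liver genes had 1 and 1 of 14 (1 and 3), female-biased genes 0 and 1 of 3 (0 and 2), genes next to Optn with the strain marker Nnt 1 and 2 of 13 (1 and 3), Kupffer cell genes 1 and 0 of 13 (1 and 0), sinusoidal endothelial genes 1 and 0 of 12 (0 and 0), stellate cell genes 0 and 1 of 13 (3 and 2), cholangiocyte genes 2 and 0 of 4 (2 and 1) and adipocyte genes 1 and 0 of 3 (1 and 0). Of 5 B cell genes, 2 sex chromosome genes and 1 pancreas gene, 0 passed in edgeR under either adjustment, 1 B cell gene had an unadjusted p under 0.05 and DESeq2 called that number in B cells. Clec4f of Kupffer cells and Stab2 of sinusoidal endothelium had log2 fold changes of 0.20 ± 0.45 and 0.11 ± 0.32 (edgeR adjusted p = 0.802 and 0.841). In the clock list the median (0.29) and mean (-0.01) differed in sign and camera pointed downward. The same held between median and mean in mitochondrial chaperones (-0.03 and 0.02, camera downward) and adipocyte genes (0.78 and -0.29, camera upward). With the library set as a term the Kupffer cell list had a median of 1.39 in place of 0.51 and passed camera upward (adjusted p = 1.73e-06). That fit in effect compares treated wild type with control replicate 3 alone, so leaving out control replicate 6 was no second check. The antioxidant, hepatocyte and T and NK cell lists no longer passed camera with that term (adjusted p = 0.139, 0.0926 and 0.126). Fewer or other genes passed in edgeR without wild-type acetaminophen replicate 4, with 2 and 1 urea cycle, 2 and 0 periportal, 0 and 1 bile acid, 1 and 1 cell cycle, 3 and 1 interferon and 1 and 1 Optn neighbour genes. EdgeR with the library set as a term passed 2 and 0 urea cycle, 0 and 1 interferon, 1 and 1 Optn neighbour, 2 and 0 sinusoidal endothelial, 2 and 0 adipocyte, 1 and 0 cholangiocyte and 4 and 0 Kupffer cell genes. The male-biased and female-biased calls were lost under both settings, and the cell cycle calls with the library set as a term.

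The split into risers and fallers depended on scaling: TMM moved all log2 fold changes by 0.22 relative to total counts, and 721 genes rose and 1470 fell without it. In limma on FPKM, as designed, 696 rose and 1496 fell, and after quantile normalization 752 and 886. The edgeR count dropped from 1667 to 812 with the library set as a term, 673 of them shared, and to 494, 806, 782 and 973 without control replicate 3, control replicate 6, wild-type acetaminophen replicate 1 and replicate 4. Of the named genes given above as risen or fallen, Optn (0.0679), Gclc (0.145), Cyp2e1 (0.0971), Fosb (0.0606), Acot3 (0.0636), Srebf1 (0.0533), Fads2 (0.0572), Glul (0.0637), Atg12 (0.106) and mt-Nd6 (0.132) had an edgeR adjusted p above the threshold with the library set as a term.

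The second comparison asks how treated livers without optineurin differ from treated wild-type livers. Few genes passed in edgeR: 6 were higher and 6 lower in knockout, Optn among the latter, of 11677 tested (edgeR adjusted p under 0.05). An unadjusted p under 0.05 was found for 1024 genes, and DESeq2 called 287. In simulated data the test recovered 19.4% of genes changed 2-fold, so smaller differences can be missed. The fatty acid ω-hydroxylases Cyp4a10 and Cyp4a14 and the gene Tmem170b, which had fallen with acetaminophen in wild type, stood near the control level in treated knockout. Cyp4a10 had a mean FPKM of 155.1 ± 10.8 in controls, 17.1 ± 2.41 in treated wild type and 199.7 ± 33.0 in treated knockout (SD, n = 2 each). These 2 treated groups lie in different library sets, so genotype and set cannot be separated among treated mice.

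Named genes higher in knockout were Tmem170b (chromosome 13, 41605907 to 41641355; log2 fold change 5.01 ± 0.25, edgeR adjusted p = 0.00475), Cyp4a14 (chromosome 4, 115486200 to 115496142; 4.77 ± 0.42, 0.0401), Cyp4a10 (chromosome 4, 115518264 to 115533649; 3.51 ± 0.21, 0.0103) and Rab30, a small GTPase of the Golgi (chromosome 7, 92741603 to 92844535; 1.91 ± 0.17, 0.0401). Cyp4a10, Cyp4a14 and Cyp4a31 are close relatives in 1 cluster, so part of their reads may be shared. Not past the threshold were Cyp4a31 (2.83 ± 0.29, edgeR adjusted p = 0.0642), Pts (1.38 ± 0.15, 0.0744), retinol saturase Retsat (1.30 ± 0.15, 0.0744) and keratin 18, Krt18 (1.04 ± 0.12, 0.0956). Lower in knockout, besides Optn, were Tpm3-rs7 (-3.04 ± 0.14, edgeR adjusted p = 0.00423), the vesicle trafficking gene Sec22c (-2.18 ± 0.20, 0.0419) and the RNA-binding protein gene Larp4 (-2.16 ± 0.19, 0.0401). Thrsp (-1.29 ± 0.13, edgeR adjusted p = 0.0637), Snrk (-1.73 ± 0.18, 0.0657), Slco1a1 (-1.04 ± 0.13, 0.133) and Cyp2a5 (-1.96 ± 0.29, 0.204) did not pass. The other 4 of the 12 genes fall outside the rule for named genes and were chosen after their values were seen. They are the processed pseudogenes Rps3a2 (-4.12) and Gm10774, and the small nuclear RNA genes Gm25679 and Gm24305. Gm10774 had 361 counts in treated wild type and 2 in knockout, a ratio of 188 (95% counting interval 51.7 to 1560). Gm24305 had 1085 counts in knockout and 2 in treated wild type, a ratio of 521 (144 to 4310). Counts of Tpm3-rs7, Rps3a2, Gm10774 and the small nuclear RNA genes are uncertain because near-identical copies can share reads.

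**Figure D4:**
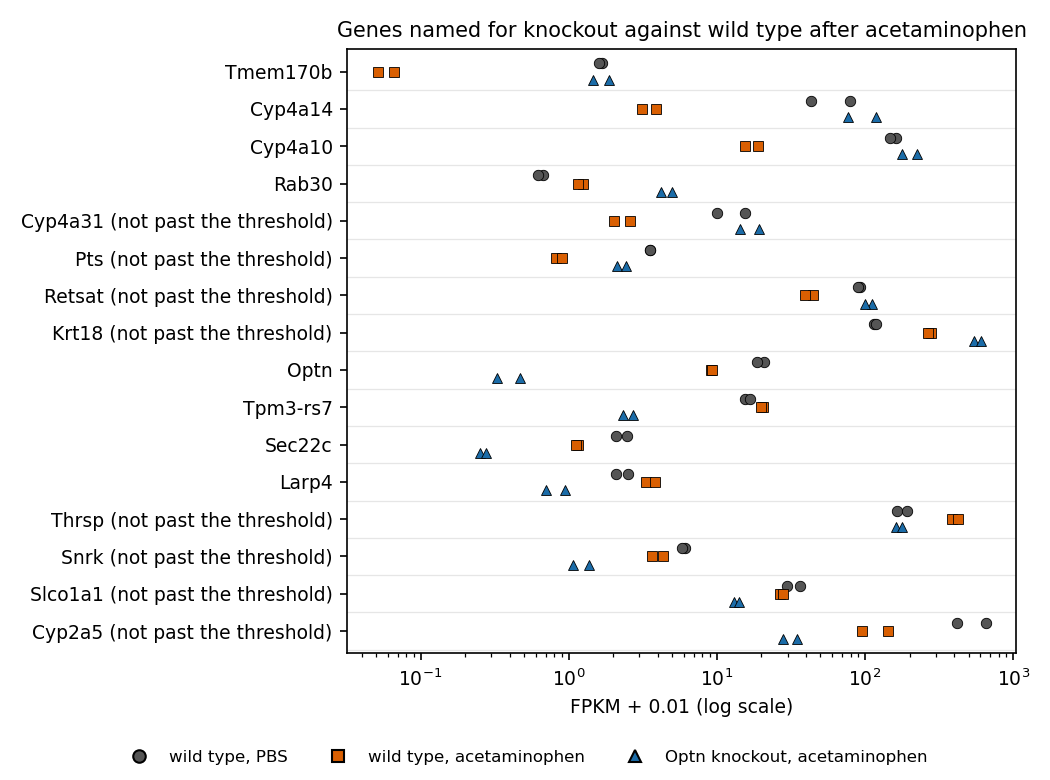
FPKM per mouse (logarithmic axis) of the 16 named genes of the knockout comparison in all 3 groups. Cyp4a10 has means of 155.1 in controls, 17.1 in treated wild type and 199.7 in treated knockout.

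Hardly any list member passed the gene test between treated knockout and wild type. Of 652 measured list genes, 2 passed in edgeR, Cyp4a10 and Cyp4a14, against 99 with an unadjusted p under 0.05, 4 calls in limma and 33 in DESeq2. The fatty acid oxidation and PPAR-alpha list was higher, with 2 of 24 genes past the test, 6 adjusted over the list alone and a median log2 fold change of 0.35 (camera adjusted p = 8.51e-08, and adjusted p = 0.454 with an estimated correlation). Vnn1 (1.79 ± 0.24, edgeR adjusted p = 0.147) and Plin2 (0.84 ± 0.15, 0.271) came next. With the library set as a term its median was 0.60. Pericentral hepatocyte genes were lower, with 0 of 19 past the test, 9 lower adjusted over the list alone and a median of -0.77 (camera adjusted p = 4.60e-09, and adjusted p = 0.454 with an estimated correlation). Cyp2c29 (-1.36 ± 0.23, edgeR adjusted p = 0.242), Rgn (-0.85 ± 0.15, 0.271) and Lect2 (-1.14 ± 0.21, 0.276) led this list, and its median was -0.40 with the library set as a term. Urea cycle and amino acid catabolism (median -0.26, camera adjusted p = 0.000103), acetaminophen bioactivation (-0.29, 0.0181), gluconeogenesis (-0.20, 0.022) and cell cycle genes (-0.25, 0.0293) were also lower, each with adjusted p = 0.454 with an estimated correlation. Heat shock (-0.26, camera adjusted p = 0.0333) and nuclear-encoded respiratory chain genes (-0.11, 0.0285) were lower too, each with adjusted p = 0.79 with an estimated correlation. Adjusted over the list alone, 1 bioactivation gene was higher and 1 lower, 3 gluconeogenesis genes were lower, and 0 members passed in the urea cycle, cell cycle, heat shock and respiratory chain lists. With the library set as a term, bioactivation, gluconeogenesis, cell cycle, heat shock and respiratory chain genes no longer passed camera (adjusted p = 0.522, 0.106, 0.596, 0.644 and 0.661), whereas the PPAR-alpha, urea cycle and pericentral lists did (2.46e-11, 0.00148 and 0.015). Without wild-type acetaminophen replicate 4, the library with neural transcripts, heat shock genes reversed to higher (camera adjusted p = 0.356), and bioactivation (0.158), gluconeogenesis (0.0815) and cell cycle genes (0.341) did not pass. Without knockout replicate 4, these 5 lists had camera adjusted p of 0.0538 to 0.174. Respiratory chain (0.689) and gluconeogenesis genes (0.0673) also failed camera without wild-type acetaminophen replicate 1, and heat shock (0.206) and cell cycle genes (0.105) without knockout replicate 5. At a mean FPKM of at least 5, heat shock (camera adjusted p = 0.0789) and respiratory chain genes (0.0634) did not pass, and too few cell cycle genes remained for a test. Among bioactivation genes, Cyp2e1 had a log2 fold change of -0.59 ± 0.19 (edgeR adjusted p = 0.509).

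Lists of immune, stromal and duct cell markers lay higher in treated knockout. Both knockout libraries also held intestinal transcripts (42.82 and 68.19 CPM), which were at most 0.30 CPM in treated wild type. Their share in the cholangiocyte markers was not tested. Camera placed markers of infiltrating monocytes (median log2 fold change 0.90, adjusted p = 0.000415), neutrophils (0.88, 0.00212), T and NK cells (0.50, 0.0142), stellate cells (0.57, 2.94e-05), cholangiocytes (1.49, 0.00372) and platelets (0.67, 0.0142) above other genes, each with adjusted p = 0.454 with an estimated correlation. Kupffer cell genes were also higher (0.45, camera adjusted p = 0.0333, and adjusted p = 0.79 with an estimated correlation). None of these markers passed over all genes in edgeR, and adjusted over the list alone 1 monocyte and 3 cholangiocyte genes did. Chil3 of the monocyte list (1.94 ± 0.27, edgeR adjusted p = 0.181), Krt19 of the cholangiocyte list (2.81 ± 0.57, 0.326) and Dcn of the stellate list (0.73 ± 0.20, 0.489) were among the leading members. S100a8 had a log2 fold change of 0.60 ± 0.44 (edgeR adjusted p = 0.749). In the control pair the same markers differed by a median of 0.66 on the log2 scale between replicates 6 and 3, which lie in different library sets. The term for the set draws on this same pair. With the set as a term the medians were 0.01 for monocytes, -0.65 for neutrophils, -0.89 for Kupffer cells, 0.51 for T and NK cells, 0.29 for stellate cells, 0.59 for cholangiocytes and 0.55 for platelets. Immediate early genes (median 0.21, camera adjusted p = 0.0181, and adjusted p = 0.454 with an estimated correlation) and cytokine genes (0.41, 0.0275, and adjusted p = 0.723 with an estimated correlation) were higher as well. So were interferon-stimulated genes (0.31, camera adjusted p = 0.0012, and adjusted p = 0.686 with an estimated correlation) and male-biased genes (0.39, 0.0192, and adjusted p = 0.657 with an estimated correlation). Adjusted over the list alone, 1 interferon gene was higher, 1 male-biased gene was higher and 1 lower, and 0 immediate early or cytokine genes passed. The cytokine list reversed to lower without wild-type acetaminophen replicate 4 (camera adjusted p = 0.88), and there neutrophil (0.158), T and NK cell (0.356), platelet (0.356), Kupffer cell (0.356), cholangiocyte (0.0594) and interferon genes (0.392) did not pass. Without knockout replicate 4, Kupffer cell (0.562), T and NK cell (0.0538), platelet (0.0669), immediate early (0.112), cytokine (0.112), interferon (0.0661) and male-biased genes (0.426) failed camera. Kupffer cell (0.0591), immediate early (0.167) and male-biased genes (0.16) failed it without wild-type acetaminophen replicate 1, and T and NK cell (0.0612) and cytokine genes (0.0965) without knockout replicate 5. Restricted to a mean FPKM of at least 5, camera did not pass monocyte (adjusted p = 0.122), neutrophil (0.243), Kupffer cell (0.102), immediate early (0.135), cytokine (0.228) or interferon genes (0.452). Too few T and NK cell, cholangiocyte and platelet genes remained there for a test, and the stellate and male-biased lists kept their calls. The set-adjusted medians of the immediate early, cytokine, interferon and male-biased lists were 0.16, -0.05, -0.01 and 0.63. With the term, no list of this paragraph passed camera in the same direction, and the Kupffer cell list passed as lower (adjusted p = 4.08e-06).

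Mitophagy, core autophagy and lysosomal lists did not pass camera in the knockout comparison. None of 23 mitophagy genes passed in edgeR over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, 0 calls in limma and DESeq2 and a median log2 fold change of -0.07 (camera adjusted p = 0.115). Pink1 had a log2 fold change of -0.07 ± 0.15 and Sqstm1 0.11 ± 0.15 (edgeR adjusted p = 0.927 and 0.874). Core autophagy (28 genes, median -0.10, camera adjusted p = 0.525) and lysosomal genes (25 genes, -0.02, 0.825) had 0 genes past the test under either adjustment. The same held for mitochondrially encoded genes (0.17, camera adjusted p = 0.218) and mitochondrial chaperones (-0.03, 0.574). Atf3 (-0.06 ± 0.14), Ddit3 (-0.30 ± 0.23), Hmox1 (0.10 ± 0.43) and Cdkn1a (0.05 ± 0.49) had edgeR adjusted p between 0.757 and 0.985, so no difference was detectable in these stress genes. The endoplasmic reticulum stress (median -0.13, camera adjusted p = 0.485), p53 (0.00, 0.953), antioxidant (0.15, 0.525), acute phase (0.29, 0.525) and metallothionein (0.06, 0.721) lists did not pass either. Neither did lipogenesis (-0.20, camera adjusted p = 0.104), cholesterol synthesis (-0.10, 0.372), bile acid (-0.16, 0.106), periportal (-0.07, 0.612), apoptosis (-0.06, 0.732) or clock genes (-0.02, 0.721). Female-biased (0.72, camera adjusted p = 0.568), sex chromosome (-0.10, 0.574), Optn neighbour (-0.05, 0.532), hepatocyte (-0.11, 0.0876), B cell (0.43, 0.057), sinusoidal endothelial (0.24, 0.117), red blood cell (0.25, 0.218) and adipocyte lists (-0.36, 0.574) were also not past the test, and the pancreas list had 1 measured gene. Adjusted over the list alone, 1 lipogenesis and 2 bile acid genes were lower, 1 apoptosis and 1 adipocyte gene were higher, and the other lists of this paragraph had 0. Some of these lists passed camera without a single library. Mitochondrially encoded genes did so without knockout replicate 4 (adjusted p = 0.00121) or wild-type acetaminophen replicate 1 (0.0394), cholesterol synthesis without knockout replicate 4 (0.00854), acute phase (0.00153) and B cell genes (0.0345) without knockout replicate 5, and red blood cell genes without wild-type acetaminophen replicate 1 (0.00028). Sinusoidal endothelial genes did so without control replicate 3 (0.0371), control replicate 6 (0.0374) or knockout replicate 5 (0.0423). Median and mean differed in sign in the lysosomal (-0.02 and 0.01), periportal (-0.07 and 0.02), apoptosis (-0.06 and 0.10), clock (-0.02 and 0.10) and metallothionein (0.06 and -0.09) lists. Camera pointed upward in the lysosomal, apoptosis, clock, metallothionein, p53 and adipocyte lists, although the mean of the p53 list was -0.02 and the adipocyte median was below 0.

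**Figure D5:**
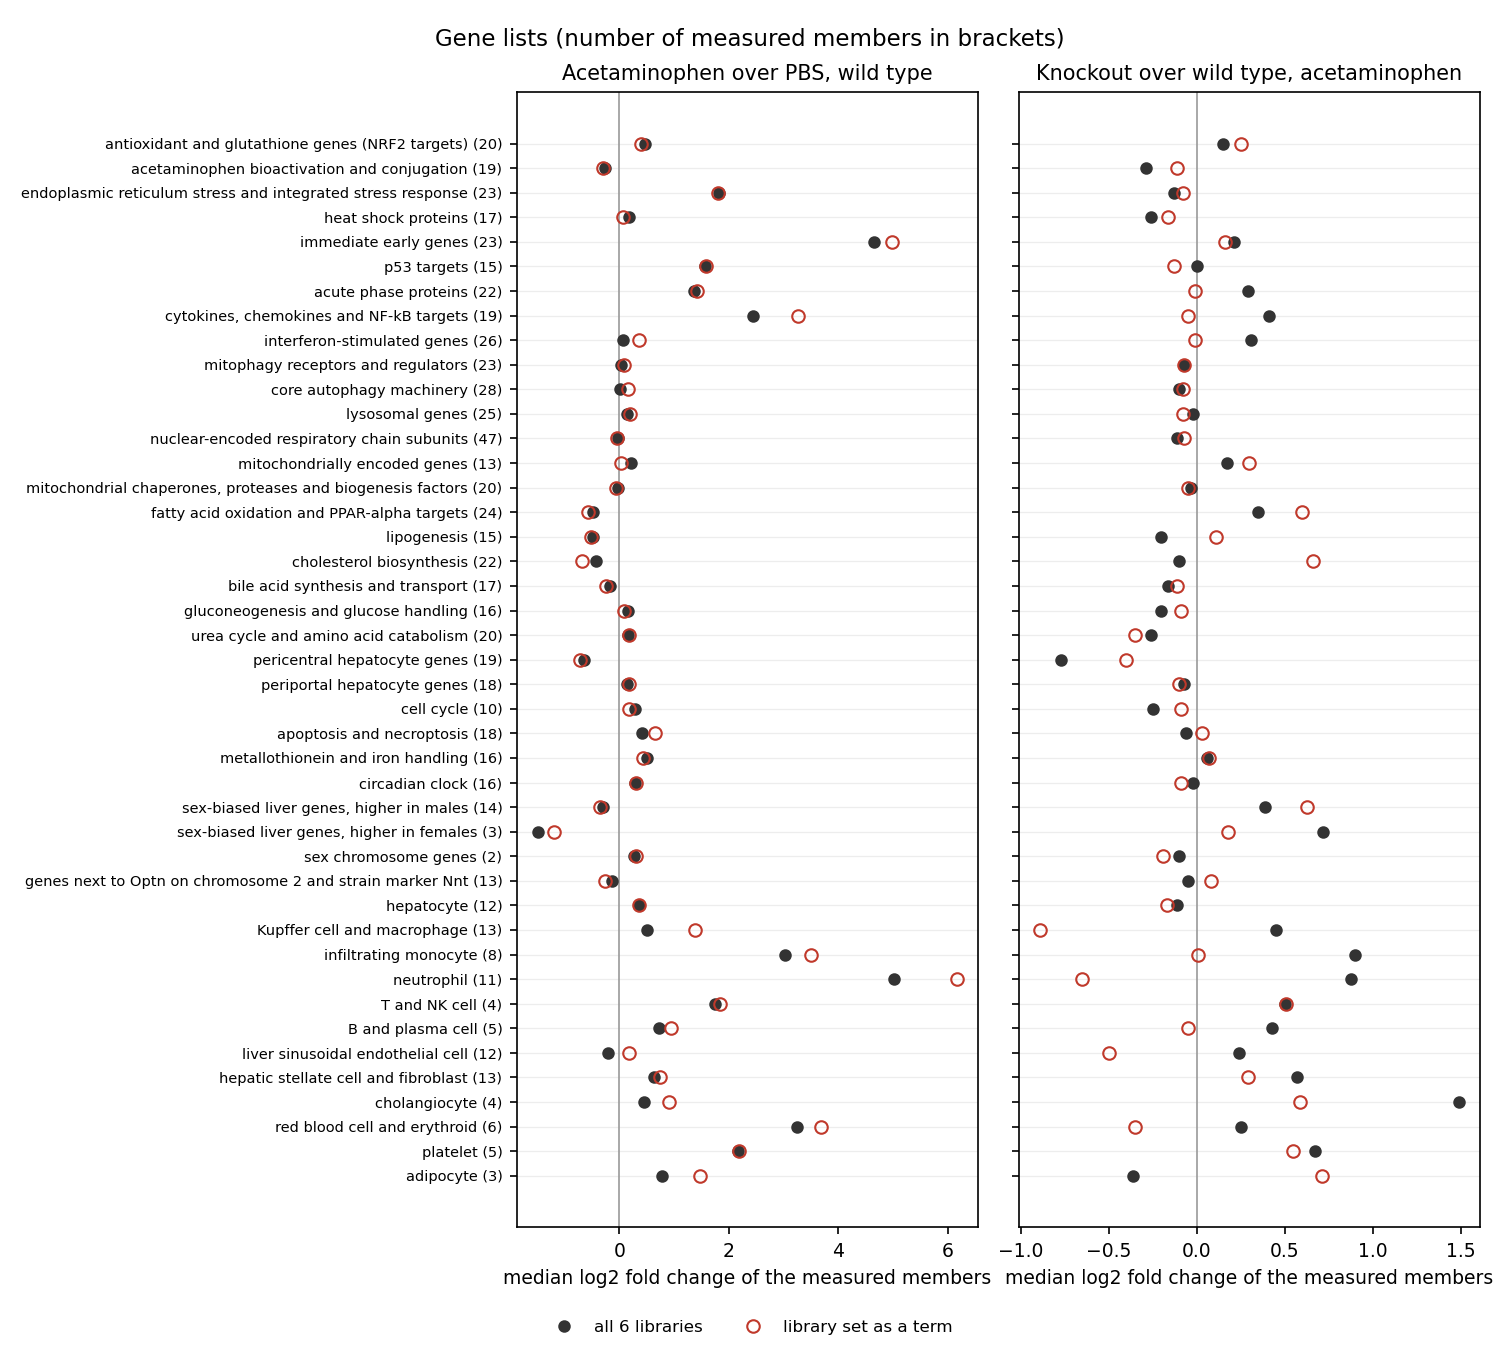
Median log2 fold change (horizontal axes) of the measured members of each gene list after acetaminophen in wild type (left) and in knockout against wild type after acetaminophen (right). Filled points use all 6 libraries and open points add the library set as a term: immediate early genes reach 4.65 on the left, and neutrophil markers move from 0.88 to -0.65 on the right.

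With the library set as a term and 2 residual degrees of freedom in place of 3, edgeR passed 0 of the 12 knockout calls. It passed 3 other genes (a second Nnt gene model, Pttg1ip and Pcyt1a, chosen after their values were seen). The set effect there comes from control replicate 6 against control replicate 3 alone, and the error of that difference enters each knockout fold. The second Nnt model went from 0.10 to 15.41, and control replicate 6 had 0 counts on it. Folds went from -4.59 to -4.40 for Optn, -3.04 to -3.13 for Tpm3-rs7, 5.01 to 5.11 for Tmem170b and 3.51 to 3.68 for Cyp4a10. They went from 4.77 to 5.68 for Cyp4a14, -4.12 to -3.84 for Rps3a2, -2.16 to -1.86 for Larp4, 1.91 to 2.06 for Rab30 and -2.18 to -1.91 for Sec22c. DESeq2 without the term called 287 genes. The fitted folds of the small nuclear RNA genes went from 7.61 to 4.69 for Gm25679 and from 8.92 to 6.00 for Gm24305, and that of Gm10774 from -7.40 to -7.16. Without knockout replicate 4, 1 gene passed, the predicted gene Gm38394, and without control replicate 3, control replicate 6, wild-type acetaminophen replicate 1, replicate 4 and knockout replicate 5 the counts were 28, 25, 6, 7 and 6.

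Treated knockout livers were also set against wild-type controls, where treatment and genotype differ together. Leading groups moved in the same direction as in treated wild type: 21 of 23 immediate early genes and 10 of 11 neutrophil markers rose, and 14 of 19 pericentral genes fell, or 20, 9 and 9 in edgeR with the library set as a term. Adjusted over the list alone, these counts were 23, 11 and 16 (camera adjusted p = 9.55e-19, 1.16e-07 and 2.06e-07, and adjusted p = 0.0856, 0.419 and 0.419 with an estimated correlation). The pericentral median was -1.69 here and -0.65 in treated wild type, where 6 of 19 fell and 1 rose. In the antioxidant list 10 of 20 genes were higher, also adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.419 with an estimated correlation), 4 with the library set as a term. That list failed camera without control replicate 6 (adjusted p = 0.137) and without either treated wild-type library (0.0601 each). Among 24 fatty acid oxidation and PPAR-alpha genes 3 were higher and 1 lower, or 3 and 0 adjusted over the list alone, and 0 were lower with the library set as a term, and camera did not pass (adjusted p = 0.698). Of 13 stellate cell genes, 7 were higher and 1 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.5 with an estimated correlation), and 1 was higher with the library set as a term. In all, 1426 genes were higher and 940 lower (edgeR adjusted p under 0.05), and limma on FPKM placed 1153 higher and 1841 lower, total-count scaling 1134 and 1756, and quantile normalization 1191 and 1290. Of 976 risers and 691 fallers in treated wild type, 900 and 548 were called in the same direction here. Independent lists would share 119.2 and 55.6, and simulated unchanged groups with the shared controls shared 0.08 and 0.01. Neither value measures the overlap that shared controls create between lists of changed genes. The first ignores the shared controls, and the second has no changed genes. The covariance of the 2 sets of log2 fold changes across genes was 0.96 against 0.119 from the shared controls alone. The Pearson correlation was 0.67 (simulated 0.49) and Spearman's rho 0.80 (simulated 0.44 to 0.48), and genes are not independent replicates.

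The acetaminophen effect in wild type and the knockout effect were set against each other across genes to see whether genes that changed with the drug differed in knockout. The covariance was -0.362, and the shared treated wild-type libraries alone gave -0.123 ± 0.010 (SD of 100 simulations). The Pearson correlation was -0.32 against a simulated -0.51 (-0.56 to -0.45), and Spearman's rho was -0.03 (simulated -0.49 to -0.45). Over the 4266 genes with a mean FPKM of at least 5 the covariance was 0.001 (simulated -0.05), so the negative value came from genes of low abundance. The shared libraries alone gave part of the covariance and a more negative correlation than was seen. These values therefore do not show that the knockout reversed the acetaminophen effect. Of the genes called for acetaminophen in wild type, 42.5% had the opposite sign in the knockout comparison. Of the 8 PPAR-alpha list genes that had fallen, 7 lay closer to the control level than to the treated wild-type level in knockout. Of 683 other fallen genes, 45 (6.6%) did so. This count was made after the results were seen, on a list that had already passed camera as higher in knockout. Cyp4a10 and Cyp4a14, which may share reads, are among the 7, and genotype and library set cannot be separated here.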

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

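The tests with the library set as a term, filterByExpr or total counts only, and the list tests without each library or with median of ratios, were chosen after seeing the data. The other settings were planned, those of the gene tests for the counts of changed genes, and were read off for Optn later. No paired analysis was possible because the groups share at most 1 replicate number. Without a library, the lone sample of its group is assumed to vary like the other groups.

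For acetaminophen in wild type, edgeR's 1667 genes became 819 at a mean FPKM of at least 5, where fewer genes are tested, 1090 with a fold of at least 2, 3107 with DESeq2 and 812 with the library set as a term. Leave-one-out counts ran from 494 (without control replicate 3) to 1263 (without knockout replicate 5), with 806, 782, 973 and 1246 without control replicate 6, wild-type acetaminophen replicates 1 and 4 and knockout replicate 4. For treated knockout against control, 2366 genes became 1035, 1535, 3620 and 960 under the same 4 settings. Leave-one-out gave 750 (without knockout replicate 5) to 2201 (without wild-type acetaminophen replicate 4), with 949, 1324 and 1350 without control replicates 3 and 6 and knockout replicate 4.

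For knockout against wild type, edgeR's 12 genes became 27 with limma as designed, 28 with a pseudocount of 1, 25 rescaled, 21 with quantile normalization, 26 without trend and 22 with array weights. They became 37 without a filter, 30 with the 4 libraries compared alone, 6 with filterByExpr, 287 with DESeq2 and 3 with the library set as a term. Leave-one-out gave 1 (without knockout replicate 4) to 28 (without control replicate 3), with 25, 6, 7 and 6 without control replicate 6, wild-type acetaminophen replicates 1 and 4 and knockout replicate 5. The cause was not tested. All 12 kept their sign in each setting that tested them, except that only 8 were tested at a mean FPKM of at least 5, where those 8 kept it, and DESeq2 called all 12.

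With an estimated correlation, camera passed 0 lists in each comparison, against 17, 19 and 22. In the knockout comparison 7 lists passed at a mean FPKM of at least 5 and 6 with the library set as a term, and leave-one-out gave 8 (without wild-type acetaminophen replicate 4) to 20 (without control replicate 3), with 9 without knockout replicate 4. With the library set as a term, cholesterol synthesis reversed to higher (camera adjusted p = 0.000487), and Kupffer cell (4.08e-06), neutrophil (0.244) and sinusoidal endothelial genes (0.0109) reversed to lower. Heat shock and cytokine genes reversed without wild-type acetaminophen replicate 4 (camera adjusted p = 0.356 and 0.88) and ranged down to 1.52e-06 without replicate 1. The cause was not tested.

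Optn kept its direction in each setting run, from -4.85 to -2.88 against -4.59. It was -3.45 in limma as designed and -2.88 with a pseudocount of 1, since a larger pseudocount shrinks the fold. It became -4.40 with the library set as a term (edgeR adjusted p = 0.0573), and leave-one-out ran from -4.85 without knockout replicate 5 to -4.36 without knockout replicate 4 (edgeR adjusted p = 0.0542). Fewer residual degrees of freedom accompany both higher p, and the set term also adds the error of 1 control library against 1. The correlation of the acetaminophen and knockout effects was -0.324, and 0.001 at a mean FPKM of at least 5, -0.126, -0.071 and -0.048 in limma with pseudocounts of 0.1, 0.5 and 1, so it depends on genes of low abundance. It was -0.456 with the library set as a term, and leave-one-out gave -0.447 (without control replicate 3) to -0.139 (without control replicate 6). At these depths a count of 0 allows 0.0388 to 0.0507 CPM.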

Other observations

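All tests in this part were chosen after the results were seen.

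Markers of 7 other cell types (58 genes) lay higher in treated knockout than in treated wild type, 58 of 58, with a median log2 fold change of 0.64; these are the lists that passed camera upward, and over all 11 such lists tested 80 of 84 markers were higher, with a median of 0.51. The library sets could account for this, since the same markers had a median log2 ratio of 0.66 between control replicates 6 and 3, with 47 of 58 higher in replicate 6, although this rests on 1 library per set. A lower share of hepatocyte RNA would raise all lists alike, and the lists moved apart (permutation p = 0.0101, and 0.00279 over the 11 lists). The permutation takes genes as independent, whereas markers of a cell type can vary together between mice. With an estimated correlation camera passed 0 lists, so this test cannot decide whether a lower hepatocyte share is the cause. The Optn genotype cannot be told apart from the library sets among treated mice. The median was -0.03 with the set as a term, a value that rests on the same control pair as the 0.66.

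Of 8 PPAR-alpha target genes that fell with acetaminophen in wild type, 7 lay nearer to the control level in treated knockout. Among the 7 were Cyp4a10, Cyp4a14 and Vnn1, and Acot1 did not lie nearer. The list had already passed camera as higher in knockout, so this count is no separate support. In the control pair the 8 genes had a median log2 ratio of -0.44, opposite to the 0.99 between treated groups. With 1 control library per set, a difference between the library sets still stays open. A smaller overall response in these knockout mice is argued against, since 45 of 683 other fallen genes (6.6%) did the same, 9.1% in knockout replicate 4 and 5.9% in replicate 5. The median was 1.76 with the set as a term, but that value draws on the same control pair and is no further support. The Optn genotype may be the source, but no knockout controls were analysed and this stays open as a hypothesis.

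Tpm3-rs7 and Rps3a2, copies of Tpm3 and Rps3a1, lost counts in treated knockout, and these genes were chosen after their values were seen. Reads shared between Tpm3-rs7 and Tpm3 would leave their sum unchanged. Tpm3 gained 1.57 times what the copy lost (4690 against 2996 normalized counts, SD of Tpm3 within groups 466), and the sum rose by 0.47 on the log2 scale. Tpm3 itself did not pass the gene test (log2 fold change 2.52 ± 0.46, edgeR adjusted p = 0.271). An exchange alone would not give a gain of that size, but the gain is not established, so shared reads stay open. For Rps3a2 the ratio was 1.08 (3258 against 3010), but the SD of Rps3a1 was 1633, so shared reads cannot be told apart from a change of the copy. The copies had a median log2 ratio of -0.09 in the control pair, against -3.58 between treated groups, but with 1 control library per set a difference between the sets stays open. A strain variant carried with the knockout stays open and untested, since the 7.9% of genes near the start of chromosome 2 with an unadjusted p under 0.05 in edgeR (8.8% elsewhere) do not bear on copies on chromosome 14 with parents on chromosome 3.

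Small nuclear RNA genes, chosen after their values were seen, gave 50.0 and 108 CPM in knockout replicates 4 and 5 and 1.95 to 3.15 elsewhere. Of 16 with at least 20 counts in both knockout libraries, 13 were over 10 times above each other library. Small nucleolar RNA genes gave 25.2 and 30.1 CPM in the knockout libraries and 14.2 to 16.6 elsewhere. Control replicate 6, in the same library set, had 1.95 CPM of small nuclear RNA, so the excess did not go with the set. Its cause, such as library preparation, was not tested. Nnt has 2 near-identical gene models, and control replicate 6 had 8689 counts on the first and 0 on the second, whereas the other libraries had 81 to 147 and 3944 to 4875, so either count is uncertain. A strain difference and a difference in read assignment cannot be separated from these counts. Control replicate 6 is also the only control in the set with intestinal traces, so values with the set as a term may carry such a difference. Saa1 had an FPKM of 2142 in knockout replicate 4 and 371.4 in replicate 5.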
